A study of Mus musculus with 20 samples.

How the data were processed

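The study holds 20 mouse libraries: RNA bisulfite sequencing and RNA-seq, each with 2 libraries of neural stem cells, of E16.5 cortical neurons in culture, and of whole brain at P0, P17 and 6 weeks. Per the labels, poly(A) RNA was selected, mixed with an unmethylated spike-in RNA of Xenopus elongation factor, converted with a kit for RNA methylation and made into stranded libraries. Samples were grouped by tissue or age and assay as the labels give them, and replicate numbers are those of the labels.

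The authors deposited gene read counts per RNA-seq library from the STAR aligner, as counts in an unstranded and 2 stranded columns. They also deposited a table of log2(TPM + 1), a normalized expression unit on the log2 scale. For the bisulfite libraries the authors deposited a call table per library with counts of covering and unconverted reads and the level as a fraction, and a site table with the same counts and the fraction for 5310 positions in all 10 libraries. The values show that the call tables list cytosines with at least 10 reads and at least 1 unconverted read, so cytosines with none are not listed. The processing notes name the genome build mm10 and R 4.1.1; the aligner of the bisulfite reads is not given in the sources used here. The spike-in was not analysed here, since the call tables cover chromosomes 1 to 19, X, Y and MT.

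Gene counts came from the reverse strand column, which held 95.9% to 96.2% of the reads in the stranded columns of every library. The totals were 11229677 to 21409014 per library. Genes were kept with edgeR's filterByExpr (17336 of 55471), scaled with TMM and fitted with robust quasi-likelihood over all 10 libraries (edgeR 4.0.16 in R 4.3.3), without covariates. The 5 residual degrees of freedom are shared over groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and counts are also given for changes of at least 2-fold. CPM are scaled to the TMM-adjusted library size. Log2 fold changes are edgeR's, with the smaller default prior count of its fit, and a prior count of 2 was used for log2 CPM only. Folds are not given where a group had no read. The SE of a log2 fold change is its size over the square root of F. The median scatter gave a biological coefficient of variation of 0.0434, and the chi-square per gene between replicates was 2.40 to 3.43, where a single library split at random would give about 1.

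Sites were tested with edgeR on unconverted and converted read counts, with a column for each library's own mean. The quasi-binomial form of the model was used, with the spread of each site estimated and squeezed over sites. It replaced a single negative binomial dispersion over all sites, which is kept as an alternative, after simulated data had shown that the latter recovered 1.52% to 36.4% of differences of 30 percentage points where the former recovered 54.6% to 72.7%. A site was tested where each of the 4 libraries of a comparison had at least 10 reads, and called at an adjusted p under 0.05; counts are also given for differences of at least 10 percentage points. In simulated RNA-seq data 88.1% to 94.0% of 2-fold changes were called, all of them placed in genes with a fitted count of at least 20. Unchanged genes made up 19 of 199 calls for neurons against neural stem cells and 20 of 195 for P17 against P0. They made up 7 of 175 calls for 6 weeks against P17 and 10 of 182 for 6 weeks against P0. Only 6 weeks against P17 stayed under the share of 0.05 that the threshold aims at.

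A site of a library is a position with at least 20 reads, at least 3 unconverted reads and a level of at least 10%. Counts of sites come from the call tables, and levels from the site table. Sites found in both libraries of at least 1 group numbered 578. Levels in the groups compared helped choose them, so counts of changed sites among them are no independent test of those groups. Measures per library were compared over the 5 groups with an exact permutation test of F, over the 945 ways to split 10 libraries into 5 pairs; a comparison of 2 groups alone cannot go below p = 0.333. Background conversion was estimated at cytosines outside the site table with at least 2000 reads and a level under 10%, with a model for counts above 0. This replaced the measure set before the data were examined, which needs cytosines with no unconverted read. Sequence context was tested with Fisher's exact test against listed cytosines with at least 100 reads and a level under 1%. Because call tables favour deeply covered cytosines, the background differs from the sites in depth. Transcript parts come from the site table and were compared between sites found in both libraries of a group and sites found in 1 library, since the other cytosines carry no part in the files used here. Of the 3336 sites that the site table assigns to a gene, 99 lie outside the feature named. All 99 fall inside it when positions are compared as text rather than as numbers, and the call tables name the same gene at 0 of them. These 99 assignments were set aside after the results had first been seen. With them, 3' UTRs held 34.4% and 20.4% of the sites (Fisher's exact test, odds ratio 2.05, p = 2.57e-13), and no call of a gene list or correlation changed. The site table assigns no gene to 1618 sites to which the call tables assign one, and those sites carry no part here. Correlations used 100000 permutations, and the adjusted p covers the 4 comparisons. The reads carry no molecular identifiers, and no counting interval is given for a count of 0.

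Before the data were examined the comparisons, tests, gene lists and the rule for named genes were fixed. The 21 lists are m5C writers, m5C erasers and readers, m6A machinery, neural stem cell and radial glia, cell cycle, immature neuron, mature neuron and synapse, glutamatergic, GABAergic, oligodendrocyte and myelin, oligodendrocyte precursor, astrocyte, microglia, endothelial cell and pericyte, fibroblast and meninges, choroid plexus and ependyma, erythroid, immediate early, cytosolic translation, oxidative phosphorylation and cholesterol synthesis. Lists were tested with camera at a preset correlation of 0.01 and at an estimated one, adjusted over the 21 lists of a comparison. Named genes are the m5C writers, erasers and readers, the 2 members of each list with the largest change, and the 3 genes with the largest rise and the 3 with the largest fall among those past the threshold with a mean log2 CPM of at least 3. Named sites are the 5 with the largest rise and the 5 with the largest fall among called sites whose replicates do not overlap, with a mean coverage of at least 20 reads, and the 5 with the highest level over all libraries. Fewer were named where fewer met the rule, and some genes that meet the rule are not reported here.

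Alternatives for genes were DESeq2's size factors in edgeR, DESeq2 1.42.0, no filter, at least 1 CPM in at least 4 libraries, the unstranded column, the 4 libraries of a comparison alone, the replicate number as a block, limma 3.58.1 on log2(TPM + 1) and on log2(TPM + 0.1), and leaving out each library. For sites they were 20 and 30 reads, Fisher's exact test, limma on arcsine square root levels, the 4 libraries alone, the block, sites found in both libraries of a group, and leaving out each library. Chosen after the data were seen were the single dispersion, the counts of the call tables, the list without sites of 6W replicate 2 alone, the restriction to sites found in both libraries of a group for the mean level, gene lists and correlations, the comparison of TCCA with GGG sites, the use of all gene assignments of the site table, and the background at 5000 reads. Work outside edgeR used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.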

Results

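Mouse RNA was measured with 2 assays in 5 groups: neural stem cells (NSC), E16.5 cortical neurons in culture, and whole brain at postnatal day 0 (P0), postnatal day 17 (P17) and 6 weeks of age (6W). RNA-seq gave gene expression. RNA bisulfite sequencing gave 5-methylcytosine (m5C), because bisulfite converts unmethylated cytosines, which are then read as T, and leaves m5C as C. Each assay had 2 libraries per group, 20 libraries in all. The reads assigned to genes in the RNA-seq libraries numbered 20593724 and 21409014 in NSC, 11229677 and 11656502 in neurons, 13768654 and 13039464 at P0, 14104958 and 16889663 at P17, and 13478128 and 15246738 at 6W. The median coverage of the 5310 positions in the authors' m5C site table ranged from 22 to 46 reads per bisulfite library. Expression is given in CPM (read counts scaled to library size) and the m5C level of a site as the percentage of covering reads with an unconverted cytosine. Values are the mean ± SD of n = 2 libraries unless another error is named, and SE marks the standard error of a log2 fold change from edgeR. The labels do not state whether the 2 replicates of a group come from separate animals or cultures, so the p-values measure the spread between these libraries.

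The first comparison asked how expression differs between cultured neurons and neural stem cells. Neuronal genes were far higher in the neuron culture. Chl1, a cell adhesion molecule of growing axons, stood at 1530 ± 65.7 CPM in neurons and had no read in either NSC library, and Neurod6, a transcription factor of excitatory cortical neurons, stood at 306 ± 0.432 CPM and also had none. Of the mature neuron and synapse genes 15 of 15 rose, of the glutamatergic genes 8 of 8 and of the GABAergic genes 9 of 10. Examples are the calcium-dependent kinase gene Camk2a, at 256 ± 13.1 CPM in neurons and 0.137 ± 0.0617 in NSC, the glutamate receptor gene Grm5, at 417 ± 20.6 and 0.183 ± 0.0605, and the GABA receptor subunit gene Gabra2, at 315 ± 33.5 CPM in neurons with no read in NSC. All 15 cell cycle genes fell, among them the mitotic kinase genes Plk1 (log2 fold change -4.07, SE 0.124) and Aurkb (-4.02, SE 0.120).

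Of 12 genes of neural stem cells and radial glia 10 fell and 1 rose. The Notch target Hes1 went from 54.4 ± 1.25 CPM in NSC to 1.74 ± 0.207 in neurons, and Vim, an intermediate filament gene of dividing precursors, from 2600 ± 46.5 to 115 ± 16.9. Of 12 immature neuron genes 11 rose and 1 fell. All 18 genes of cytosolic translation fell, such as the ribosomal protein gene Rplp2, at 0.203 times its NSC level. Of 12 cholesterol synthesis genes 11 rose and 1 fell, with Hmgcs1, an early enzyme of the pathway, 5.21-fold higher in neurons. Of 10 immediate early genes 8 fell and 1 rose, with Egr1 at 123 ± 18.6 CPM in NSC and 6.10 ± 0.140 in neurons. Of 13 oxidative phosphorylation genes 9 rose and 2 fell.

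Markers of other cell types moved as well. The collagen gene Col1a2 stood at 834 ± 25.7 CPM in NSC and 0.731 ± 0.238 in neurons, and 4 of 5 genes of fibroblasts and meninges fell while 1 rose. Glial transcripts were measured in the neuron culture: of 11 astrocyte genes 7 rose and 2 fell, of 7 oligodendrocyte precursor genes 4 rose and 3 fell, and of 12 oligodendrocyte and myelin genes 3 rose and 4 fell. The astrocyte water channel gene Aqp4 stood at 70.2 ± 9.07 CPM in neurons and 1.88 ± 0.604 in NSC, the precursor gene Gpr17 at 49.0 ± 26.6 and 0.0679 ± 0.0960, and the myelin gene Mbp at 40.4 ± 6.44 and 0.965 ± 0.106. All 6 genes of choroid plexus and ependyma rose, with the thyroxine carrier gene Ttr at 78.2 ± 14.9 CPM in neurons and 0.744 ± 0.604 in NSC. Of 10 microglial genes 6 rose and 3 fell, and of 9 endothelial and pericyte genes 2 fell; none of 4 erythroid genes passed the threshold. The sex of the cells differed too: Xist, the RNA of the inactive X chromosome, had 5947 and 4238 reads in the neuron libraries and 1 to 17 in the other 8, while the Y-linked gene Ddx3y had 302 and 184 reads in the neuron libraries and 1413 to 1851 in the other 8.

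In edgeR's quasi-likelihood test 13540 of 17336 genes passed an adjusted p of 0.05, 6607 higher and 6933 lower in neurons; 8566 of them changed at least 2-fold, 4522 higher and 4044 lower. With DESeq2 more genes were higher (6591) than lower (6069). The largest rises among well expressed genes were those of Chl1, of the axonal adhesion gene Cntn1 and of the calcium-binding protein gene Caln1, and the largest falls those of Fndc3c1 (log2 fold change -12.71, SE 0.136), Col1a2 (-10.13, SE 0.124) and Mxra8 (-8.80, SE 0.158). In the camera test the lists of mature neuron and synapse, glutamatergic, GABAergic and cell cycle genes passed with both the preset and an estimated correlation, the last with adjusted p = 2.46e-15 and 0.0157. The calls of 5 lists were lost with an estimated correlation: adjusted p = 0.0599 for neural stem cell, 0.0764 for immature neuron, 0.388 for fibroblast, 0.552 for translation and 0.619 for cholesterol genes. Counts adjusted over the list alone were equal to those above except for astrocyte genes, where 10 changed in place of 9. For the oligodendrocyte precursor and microglia lists the median and mean changes were above 0 while camera pointed down, without passing.

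The second comparison asked which m5C sites differ between neurons and NSC. Most sites that changed were more methylated in neurons. The site in an exon of Psd, which encodes an exchange factor for the small GTPase Arf6, stood at 46.7 ± 0.460% in neurons and 4.55 ± 6.43% in NSC (chromosome 19, position 46312826, minus strand of mm10). An exon site of Rnf157, a ubiquitin ligase gene, stood at 69.9 ± 2.95% and 40.3 ± 1.82% (chromosome 11, position 116358680), and a 3' UTR site of Samd14 at 41.8 ± 0.560% and 11.4 ± 1.46% (chromosome 11, position 95025131). A 3' UTR site of Wdr48, a cofactor of deubiquitinases, rose by 27.3 percentage points, and a 5' UTR site of Med24, a Mediator subunit gene, by 24.4. In the other direction, mitochondrial position 911, inside the 12S ribosomal RNA gene mt-Rnr1 (70 to 1024), stood at 42.0 ± 1.24% in neurons and 67.9 ± 1.79% in NSC.

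Of 2395 sites with at least 10 reads in each of the 4 libraries, 65 passed edgeR's test, 59 higher and 6 lower in neurons, and 24 of them differed by at least 10 percentage points. The 6 named sites were covered by 22 to 4733 reads per library, and their adjusted p in edgeR ranged from 1.34e-17 (Samd14) to 0.00549 (Wdr48). Among the 375 tested sites found in both libraries of a group, 127 passed, 124 higher and 3 lower, but levels in the groups compared helped choose these sites. Simulated increases of 30, 20 and 10 percentage points, placed at sites with a mean of at least 20 reads, were called at 72.7%, 49.3% and 22.4% of these sites. Smaller differences were thus mostly not detectable even at that depth. In the 3 brain comparisons differences of 20 points were called at 20.9% to 47.8% of such sites and differences of 10 points at 2.99% to 5.97%. The count depended on the test, from 7 sites with limma on transformed levels to 525 with Fisher's exact test on summed reads, which ignores the spread between replicates.

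The third comparison asked how the brain changes between P0 and P17. Genes of myelin, glia and mature synapses rose, and genes of dividing and immature cells fell. All 12 oligodendrocyte and myelin genes rose: Mobp, a myelin protein gene, went from 1.09 ± 0.747 to 1550 ± 109 CPM and Mog from 0.0368 ± 0.0520 to 306 ± 8.40. All 10 microglial genes rose, with the purine receptor gene P2ry12 11.7-fold higher, and of 11 astrocyte genes 9 rose and 1 fell, with the glutamate transporter gene Slc1a2 at 275 ± 28.8 CPM at P0 and 4700 ± 58.0 at P17. All 15 mature neuron and synapse genes rose, such as Camk2a, 14.6-fold higher.

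All 15 cell cycle genes fell, with Aurkb at 0.0662 times its P0 level, and of 12 immature neuron genes 11 fell and 1 rose, with Dpysl3, a cytoskeletal gene of growing axons, at 0.0568 and the transcription factor gene Sox11 at 0.0601 times their P0 levels. Of 12 neural stem cell and radial glia genes 8 fell and 1 rose, and Fabp7, the fatty acid binding protein of radial glia, went from 653 ± 12 to 96.4 ± 1.92 CPM. Of 8 glutamatergic genes 5 rose and 2 fell, and of 10 GABAergic genes 8 rose and 1 fell; the vesicular glutamate transporter gene Slc17a7 was 18.4-fold and the interneuron gene Pvalb 115-fold higher. All 13 oxidative phosphorylation genes rose, with the succinate dehydrogenase gene Sdha 2.21-fold higher, and 17 of 18 translation genes fell, with Rplp0 at 0.362 times its P0 level. Of 7 oligodendrocyte precursor genes 4 rose and 1 fell, and 7 of 10 immediate early genes and all 4 erythroid genes rose, with the globin gene Hbb-bs at 47.5 ± 14.9 CPM at P17. All 5 genes of fibroblasts and meninges fell, with Col3a1 at 0.205 times its P0 level. Of 9 endothelial and pericyte genes 5 fell and 2 rose, of 6 choroid plexus genes 2 fell and 1 rose, and of 12 cholesterol synthesis genes 7 rose and 4 fell.

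In edgeR 12232 of 17336 genes passed, 6182 higher and 6050 lower at P17, and 5505 changed at least 2-fold. The balance of directions turned with limma, which called 5153 higher and 7155 lower on log2(TPM + 1), and 4889 and 6740 on log2(TPM + 0.1). The largest falls among well expressed genes were those of the imprinted RNA H19 (log2 fold change -5.77, SE 0.156), of St8sia2, which adds polysialic acid to the adhesion molecule of young neurons (-5.06, SE 0.079), and of Draxin, an axon guidance gene (-4.21, SE 0.112). In camera, myelin genes passed with adjusted p = 1.3e-76 and, with an estimated correlation, 0.00606. The lists of cell cycle, immature neuron, mature neuron, glutamatergic, GABAergic and astrocyte genes and of m5C erasers and readers also passed both ways. The calls of 5 lists were lost with an estimated correlation: adjusted p = 0.101 for neural stem cell, 0.111 for microglia, 0.101 for fibroblast, 0.134 for translation and 0.125 for oxidative phosphorylation genes. Counts adjusted over the list alone were equal to those above except for neural stem cell genes (10 changed), astrocyte genes (11) and immediate early genes (8).

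**Figure D1:**
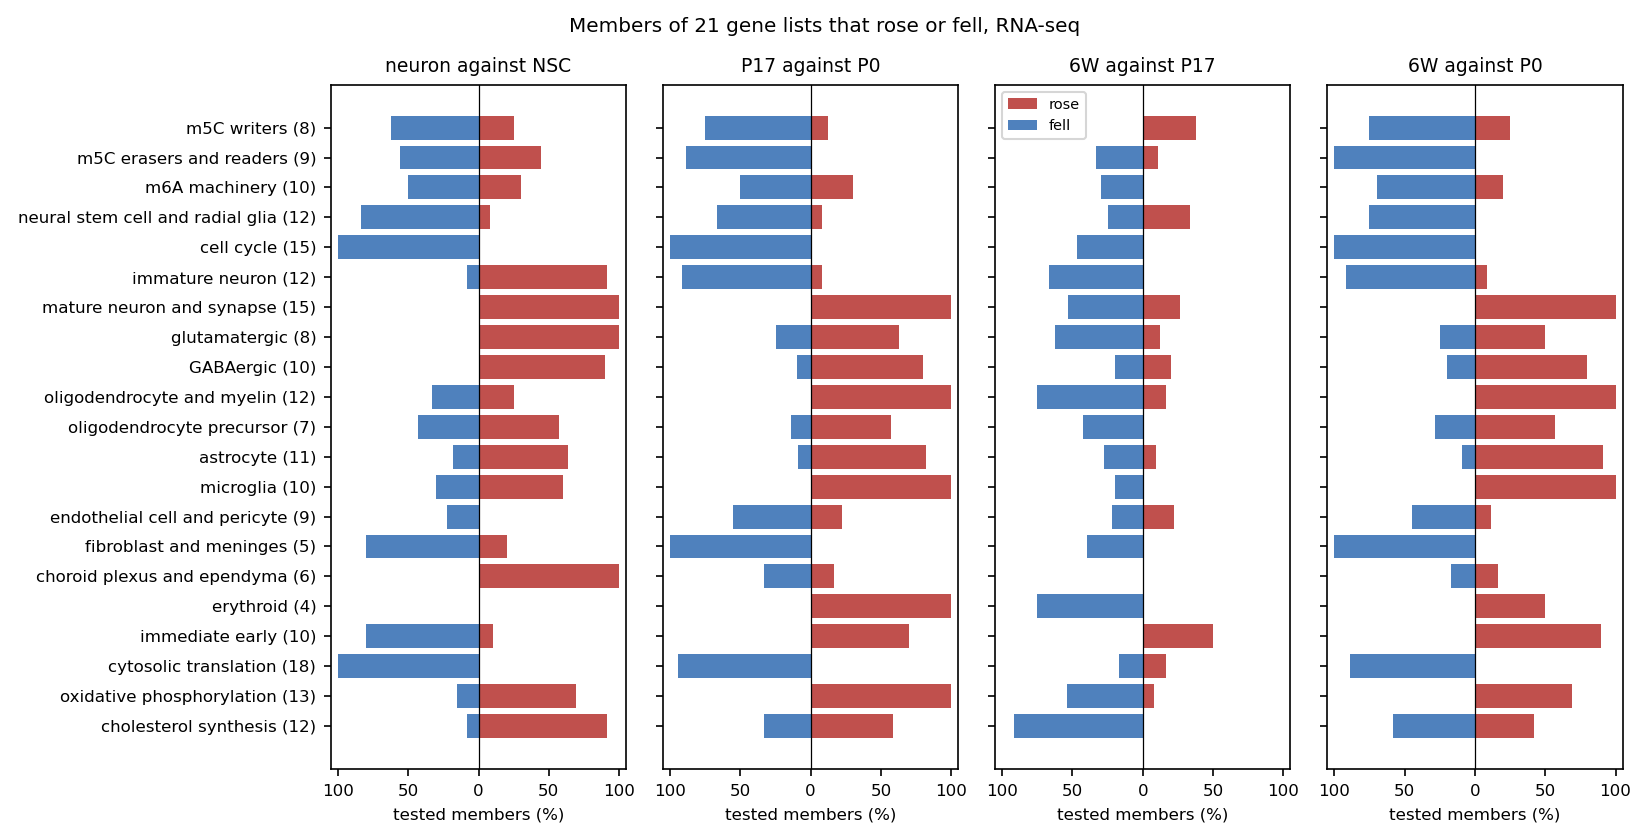
Share of the tested members of 21 gene lists that rose (red) or fell (blue) past an adjusted p of 0.05 in edgeR in each comparison; the number in brackets is the number of members tested. All 12 oligodendrocyte and myelin genes were higher at P17 and at 6W than at P0, and 9 of them were lower at 6W than at P17.

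The next comparison asked which m5C sites differ between P0 and P17, and sites moved in both directions. An exon site of Chd3, a chromatin remodeller gene, rose from 6.36 ± 0.370% to 48.2 ± 4.17% (chromosome 11, position 69360286, minus strand), and an exon site of Homer3, a postsynaptic scaffold gene, from 1.58 ± 0.740% to 34.7 ± 3.44% (chromosome 8, position 70289439). The Psd site rose from 25.9 ± 0.440% to 50.4 ± 0.480%, and 3' UTR sites of Ntsr1, a neurotensin receptor gene, and of Rgs8, a regulator of G protein signalling, rose by 27.4 and 21.4 percentage points. An exon site of Map6, which stabilises microtubules, dropped from 66.8 ± 1.99% to 13.4 ± 5.28% (chromosome 7, position 99318553), and an exon site of Csf1r, the growth factor receptor of microglia, from 81.2 ± 6.07% to 33.2 ± 4.35% (chromosome 18, position 61129085).

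A 3' UTR site of Sdc3, a syndecan gene (chromosome 4, position 130824055), dropped from 74.4 ± 2.04% to 40.6 ± 1.20%, an exon site of Bag6, a chaperone gene, from 51.4 ± 2.06% to 23.6 ± 7.32%, and a 3' UTR site of Cend1, a gene of neuronal cell cycle exit, from 37.3 ± 2.70% to 11 ± 2.38%. The cytosines in Csf1r, Sdc3 and Bag6 are each followed by TCCA. Of 3266 sites tested 91 passed in edgeR, 57 higher and 34 lower at P17, and 42 differed by at least 10 percentage points. The 10 named sites had adjusted p values in edgeR from 6.49e-75 (Psd) to 0.00957 (Cend1). Among the 479 tested sites found in both libraries of a group, 204 passed, 122 higher and 82 lower, with the same limit on the choice of sites. Limma on transformed levels called 0 sites, with 294 at an unadjusted p under 0.05, and Fisher's exact test on summed reads called 660.

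**Figure D2:**
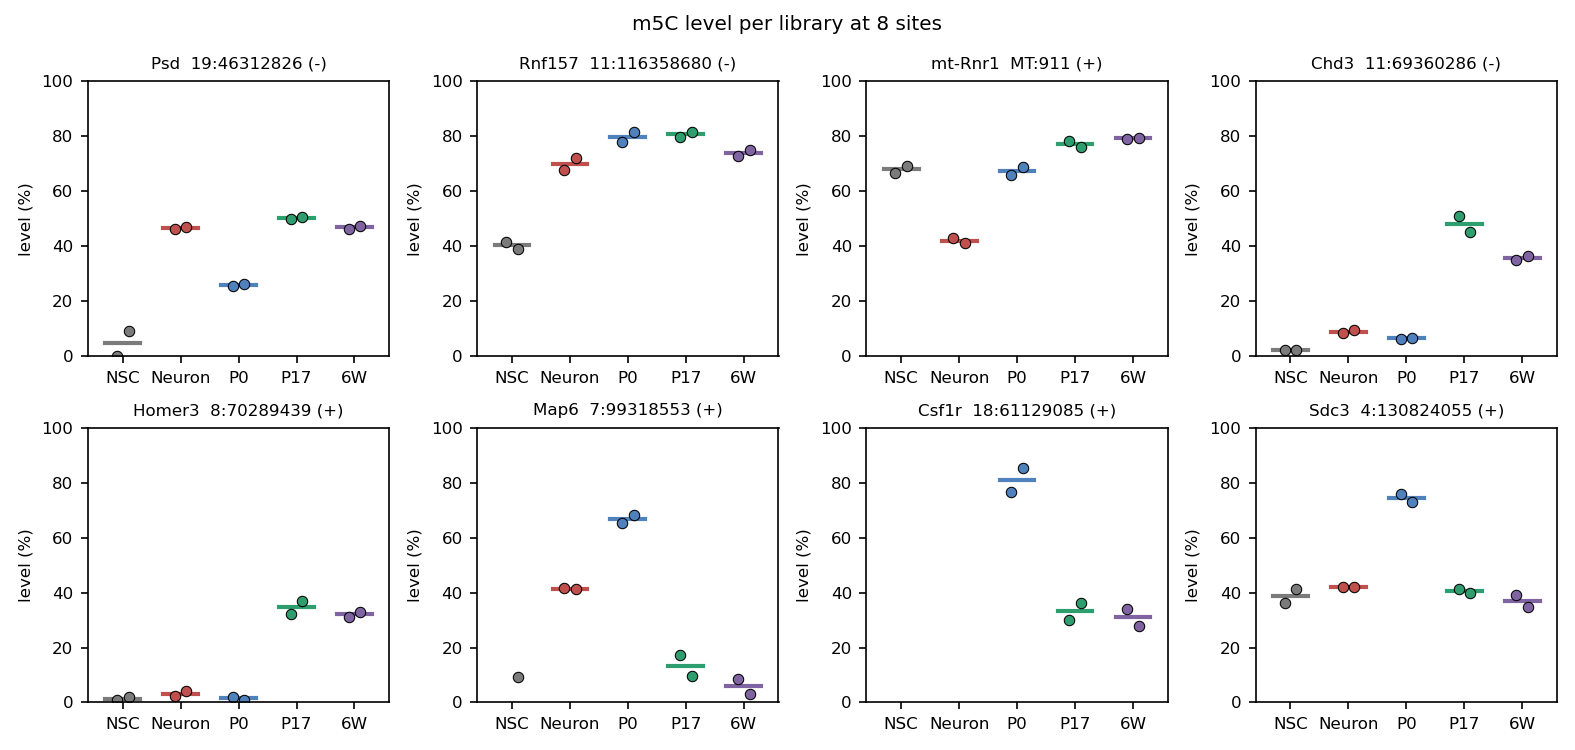
m5C level at 8 sites (percentage of reads unconverted) in each bisulfite library with at least 10 reads at the site; points are libraries and lines are group means. The sites in Map6, Csf1r and Sdc3 were highest at P0, while those in Chd3 and Homer3 were highest at P17.

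From P17 to 6W expression changed less. Of 12 myelin genes 9 fell and 2 rose, and 11 of 12 cholesterol synthesis genes fell; both lists passed camera with the preset correlation and neither with an estimated one (adjusted p = 0.106 for each). Ugt8a, which makes the myelin lipid galactosylceramide, went from 564 ± 12 to 187 ± 8.89 CPM, Mog from 306 ± 8.40 to 154 ± 5.36 and Hmgcs1 from 798 ± 24.7 to 385 ± 15.7. Of 12 immature neuron genes 8 fell, with Dpysl3 at 0.449 times its P17 level, and 3 of 7 oligodendrocyte precursor genes fell, with Gpr17 at 0.297. The nuclear RNA Neat1 was 5.93-fold higher at 6W, at 96.7 ± 2.61 CPM, and the immediate early gene Npas4, induced by neuronal activity, 2.54-fold higher.

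Of 10 immediate early genes 5 rose, 3 of 4 erythroid genes fell, 7 of 15 cell cycle genes fell, and of 13 oxidative phosphorylation genes 7 fell and 1 rose. Of 15 mature neuron and synapse genes 8 fell and 4 rose, by less than 2-fold for the most changed, the neurofilament gene Nefm (log2 fold change -0.56, SE 0.060). Of 8 glutamatergic genes 5 fell and 1 rose, and of 11 astrocyte genes 3 fell and 1 rose. Among well expressed genes the largest rises besides that of Neat1 were those of Igfn1 (4.33-fold) and Crtam (3.77-fold), and the largest falls those of 9630013A20Rik (log2 fold change -2.65, SE 0.108) and of the globin genes Hbb-bs (-2.07, SE 0.206) and Hbb-bt (-1.94, SE 0.273). In edgeR 5519 genes passed, 2351 higher and 3168 lower at 6W, and 546 changed at least 2-fold, 335 higher and 211 lower. Which direction held more genes depended on the method: limma on log2(TPM + 1) called 2566 higher and 1875 lower, and on log2(TPM + 0.1) 1862 and 1572. Without P17 replicate 2 edgeR called 3538 genes.

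In camera 8 lists passed in this comparison, none of them with an estimated correlation, where adjusted p = 0.106 for immature neuron genes as for myelin and cholesterol genes, 0.122 for oligodendrocyte precursor, 0.242 for cell cycle and oxidative phosphorylation, and 0.257 for erythroid and immediate early genes. Counts adjusted over the list alone were larger for translation genes (10 in place of 6), astrocyte genes (6 in place of 4), and, by 1 gene each, cell cycle, immediate early and oxidative phosphorylation genes.

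Against P0, the 6W brain showed 12630 changed genes in edgeR, 6387 higher and 6243 lower, of which 5934 changed at least 2-fold; limma on log2(TPM + 1) called 5782 higher and 6785 lower. The 15 mature neuron and synapse, 12 myelin and 10 microglial genes all rose, as did 10 of 11 astrocyte genes and 9 of 10 immediate early genes, while all 15 cell cycle genes, all 5 fibroblast and meninges genes and 11 of 12 immature neuron genes fell. Scn4b, a sodium channel subunit gene, went from 1.44 ± 0.453 to 266 ± 15.4 CPM, and Cbln3, a gene of cerebellar granule cells, from 1.51 ± 0.151 to 248 ± 7.16. H19 went from 120 ± 8.28 to 0.653 ± 0.0961 CPM. In camera the 8 lists that passed both ways between P0 and P17 did so here too, glutamatergic genes with adjusted p = 0.0444 with an estimated correlation. With the replicate number as a block none of these 8 lists passed camera with an estimated correlation, either between P0 and P17 (lowest adjusted p = 0.0573) or here (0.0642). Without the block the calls of 5 lists were lost with an estimated correlation: adjusted p = 0.13 for neural stem cell and microglia, 0.105 for fibroblast, 0.314 for immediate early and 0.192 for translation genes. Counts adjusted over the list alone were equal to the counts over all genes for every list.

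The m5C comparison of P17 and 6W gave few called sites. A 3' UTR site of Mobp rose from 8.98 ± 2.71% to 24.5 ± 0.430% (chromosome 9, position 120179717), a 3' UTR site of Bok, a Bcl-2 family gene, from 14.9 ± 2.90% to 27.0 ± 5.07%, and an exon site of Rapgef4, an exchange factor gene that responds to cyclic AMP, from 11.2 ± 1.80% to 20.1 ± 3.03%. Sites of the kinase gene Map4k4 and the ribosomal protein gene Rps9 rose by 5.67 and 5.50 percentage points. Sites of the Golgi protein gene Glg1, the synaptic vesicle gene Syp and the actin bundling gene Fscn1 dropped from 26.6 ± 0.05% to 16.9 ± 2.10%, from 26.6 ± 3.75% to 18.6 ± 0.00320% and from 19.2 ± 0.150% to 11.3 ± 1.27%, and those of Abr and Mapk8ip1 dropped by 7.67 and 6.39 percentage points. In edgeR 18 of 3726 sites passed, 6 higher and 12 lower at 6W, 2 of them by at least 10 percentage points. Fisher's exact test on summed reads, which ignores the spread between replicates, gave the opposite balance, with 963 higher and 445 lower. The median difference over the tested sites was 2.35 percentage points upward. It was 0 without 6W replicate 2, and 0 without the sites that met the rule in that library alone, so this upward median rested on 1 library. Simulated differences of 10 points were called at 5.97% of the sites that carried them, so that few calls do not show few changes. Without 6W replicate 2 edgeR called 7 sites. Among the 515 tested sites found in both libraries of a group, 63 passed, 11 higher and 52 lower. High levels at P17 helped choose more of these sites (301) than high levels at 6W (261), so this balance cannot decide the direction.

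Between P0 and 6W 98 of 3595 sites passed in edgeR, 47 higher and 51 lower at 6W, and 58 differed by at least 10 percentage points. The balance turned with Fisher's exact test on summed reads, 1080 higher and 414 lower, and with a single dispersion, 49 and 34. The median difference over the tested sites was 5.04 percentage points upward, and 0 without 6W replicate 2. The Homer3, Chd3 and Rgs8 sites were higher than at P0 by 30.5, 29.2 and 24.9 percentage points and the Bok site by 26.7. A 3' UTR site of Mxra7 stood at 0.740 ± 1.04% at P0 and 52.8 ± 25.2% at 6W, with 20 to 68 reads per library. The Map6 site stood at 5.87 ± 3.77% at 6W, the Csf1r site at 31 ± 4.46%, the Sdc3 site at 37.1 ± 3.11% and the Cend1 site at 1.52 ± 0.610%, all lower than at P0, and an exon site of Igfbp6, a growth factor binding protein gene, stood at 34.9 ± 23.0% at P0 (51.1% and 18.6% in the 2 libraries) and 3.04 ± 0.270% at 6W. Among the 506 tested sites found in both libraries of a group, 215 passed, 96 higher and 119 lower, and here too levels in the groups compared helped choose the sites.

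The genes that write, read and remove m5C were followed through all 5 groups. Nsun2 (ENSMUSG00000021595), which encodes a main writer of m5C in messenger RNA, stood at 101 ± 0.721 CPM in NSC, 112 ± 0.972 in neurons, 95.8 ± 0.491 at P0, 74.5 ± 1.71 at P17 and 76.3 ± 1.96 at 6W. Nsun6 (ENSMUSG00000026707), whose product methylates cytosines followed by TCCA, stood at 7.80 ± 1.43, 11.9 ± 1.91, 17.1 ± 1.77, 9.10 ± 0.302 and 9.28 ± 0.190 CPM. Of the 8 writer genes 5 fell and 2 rose from NSC to neurons, 6 fell and 1 rose from P0 to P17, and 3 rose from P17 to 6W. The list passed camera in none of the 4 comparisons (adjusted p = 0.741, 0.121 and 0.16 for these, and 0.35 for 6W against P0). With the replicate number as a block it passed downward from P0 to P17 (camera adjusted p = 0.0482), but not with an estimated correlation (0.151). Between P0 and P17 Nsun2 had a log2 fold change of -0.36 (SE 0.064), Nsun6 of -0.92 (SE 0.148), Nsun5, a writer for ribosomal RNA, of -1.58 (SE 0.153) and Trdmt1, a writer for transfer RNA, of -1.39 (SE 0.145), while Nsun4, a mitochondrial writer, rose (0.40, SE 0.148). Of 9 genes of m5C erasers and readers 8 fell from P0 to P17 (camera adjusted p = 9.62e-05, and 0.0239 with an estimated correlation). The reader genes Ybx1 and Alyref had log2 fold changes of -2.24 (SE 0.057) and -1.62 (SE 0.086). From NSC to neurons 4 of these 9 rose and 5 fell, and from P17 to 6W 1 rose and 3 fell. Of 10 genes of the m6A machinery, a control list for another RNA mark, 5 fell and 3 rose both from NSC to neurons and from P0 to P17.

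The number of m5C sites per library was compared across the 5 groups, a site being a position with at least 20 reads, 3 unconverted reads and a level of 10%. Both NSC libraries were low, with 3931 and 3935 sites, while neurons had 7121 and 4346, P0 6265 and 4627, P17 5679 and 4519, and 6W 6725 and 21741. An exact permutation test of F over the 945 ways to split 10 libraries into 5 pairs gave p = 0.164. The authors' site table holds 228 to 2927 of these sites per library, so in every library most of the positions counted lie outside it. Over its positions with 20 reads in all 10 libraries the counts were 91 and 89 in NSC, 249 and 220 in neurons, 252 and 239 at P0, 318 and 277 at P17 and 261 and 581 at 6W (exact permutation p = 0.0339), and over all its positions the exact permutation p was 0.1619. Few sites of the table recurred: of its 5310 positions 4483 met the rule in 1 library and 2482 of these in 6W replicate 2, while 578 met it in both libraries of at least 1 group. Those found in both libraries numbered 108 in NSC, 201 in neurons, 258 at P0, 301 at P17 and 261 at 6W, and 37 were found in both libraries of all 5 groups.

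The mean level over the 2073 table positions with 10 reads in every library was 2.08 ± 0.0226% in NSC, 4.12 ± 0.538% in neurons, 3.90 ± 0.119% at P0, 4.50 ± 0.618% at P17 and 6.11 ± 3.02% at 6W (exact permutation p = 0.127). With 1 library left out the exact permutation p was 0.0074 without 6W replicate 1, which leaves the outlying replicate 2 alone in its group, 0.0698 without 6W replicate 2, and 0.2053 to 0.3481 without any other. Over 346 sites found in both libraries of a group, an alternative chosen after the data were seen, it was 8.17 ± 0.0692% in NSC, 14.2 ± 0.192% in neurons, 14.6 ± 0.00281% at P0, 16.3 ± 0.702% at P17 and 14.6 ± 0.348% at 6W (exact permutation p = 0.0063). Agreement within the real groups chose these sites, and the permuted splits do not repeat that choice, so this p cannot test the groups. The unconverted share at deeply covered cytosines outside the table, a measure of background, was 0.0757% to 0.0946% in the 10 libraries, with the neurons highest (exact permutation p = 0.0212). That call was lost without any single NSC, neuron, P0 or P17 library, with exact permutation p between 0.0571 and 0.126.

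**Figure D3:**
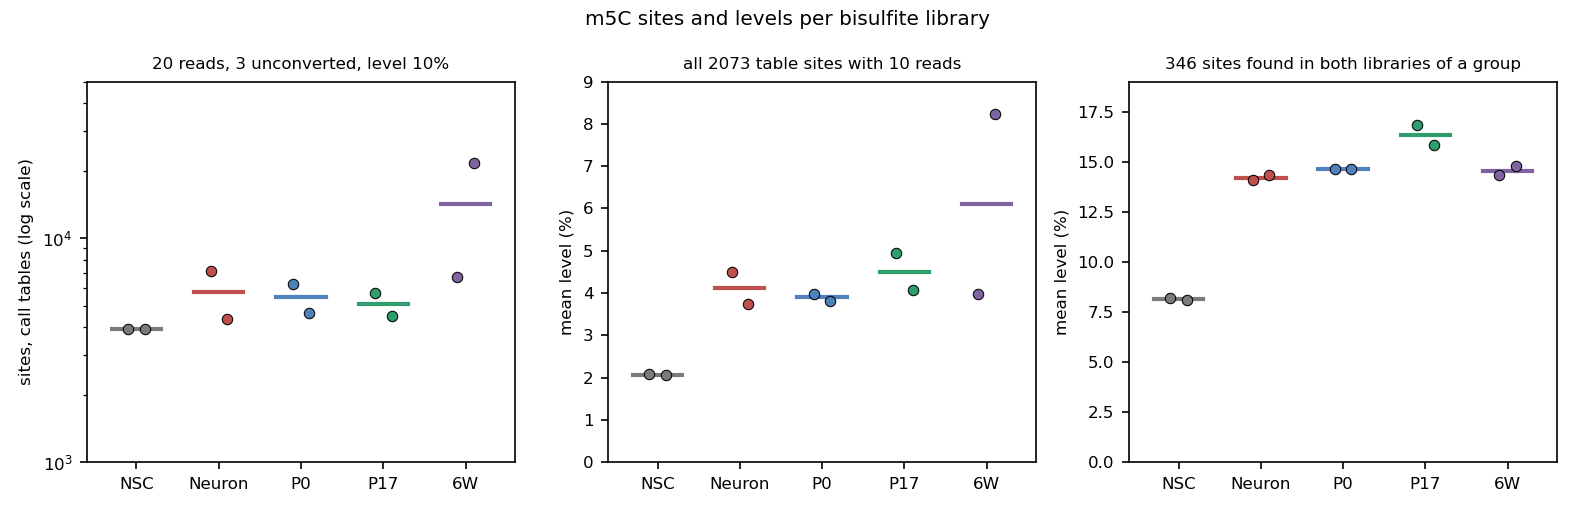
Number of m5C sites in each bisulfite library (left, log scale) and mean m5C level in percent over all table positions with 10 reads in every library (middle) and over sites found in both libraries of a group (right); points are libraries and lines are group means. 6W replicate 2 stands apart in the left and middle panels, at 21741 sites, and NSC is lowest in all 3. Most positions counted in the left panel lie outside the authors' site table.

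Over all 10 libraries the highest level was at a 3' UTR site of Nisch, which encodes an imidazoline receptor protein (86.3% on average, chromosome 14, position 31186632, minus strand, 60 to 515 reads). It was followed by a site on chromosome 10 (position 77979895, 80.1%) that the call tables assign to 1810043G02Rik, the Rnf157 site (68.9%), mitochondrial position 911 (66.8%) and a site on chromosome 15 (position 62259301, 50.7%) that they assign to the noncoding RNA gene Pvt1. The site table names no transcript part for the last site, and an unrelated gene for the one on chromosome 10.

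By sequence, the table positions that met the rule in a library were set against listed cytosines outside the table with at least 100 reads and a level under 1%. Positions followed by GGG at +2 to +4, the context of Nsun2, made up 6.03% to 20.1% of the sites and 1.71% to 1.89% of background cytosines, and those followed by TCCA at +1 to +4, the context of Nsun6, 1.78% to 9.13% and 0.733% to 0.859%. Both contexts were enriched in each of the 10 libraries. Odds ratios ran from 3.4 to 14.2 for GGG and from 2.23 to 12.1 for TCCA, and the highest adjusted p was 1.56e-28 for GGG, in NSC replicate 2, and 0.00294 for TCCA, in neuron replicate 2 (Fisher's exact test). GGG was found at 24.1% of the sites seen in both libraries of a group and at 4.44% of those seen in 1 library (Fisher's exact test, odds ratio 6.82, p = 7.47e-49), and TCCA at 7.96% and 1.36% (Fisher's exact test, odds ratio 6.27, p = 4.68e-17). Of the sites seen in both libraries of a group 34.4% lay in 3' UTRs, against 19.7% of those seen in 1 library (Fisher's exact test, odds ratio 2.14, p = 1.05e-14). Exons held 34.8% and 34.5%, and sites with no annotated part made up 25.4% and 41.5%. These are shares of all sites, so the uneven share with no part can move those of exons and 3' UTRs. In 6W replicate 2, which holds most sites seen in 1 library, 46.8% had no part and 19.3% lay in 3' UTRs.

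TCCA sites followed a course of their own. Over the 34 TCCA sites found in both libraries of a group the mean level was 6.24 ± 0.0830% in NSC, 7.67 ± 0.529% in neurons, 17.9 ± 0.278% at P0, 12.2 ± 0.0520% at P17 and 10.7 ± 0.452% at 6W. Over the 70 GGG sites it was 9.99 ± 0.0540%, 15.5 ± 0.251%, 14.4 ± 0.269%, 17.2 ± 1.41% and 15.6 ± 0.750%. From P0 to P17 TCCA sites changed by -5.69 percentage points on average (SE 1.80 over sites, 24 of 34 lower) and GGG sites by 2.78 (SE 0.987, 47 of 70 higher). The difference of -8.47 points had a permutation p of 1e-05, the smallest the permutations can give, and an adjusted p of 4e-05 over the 4 comparisons. From NSC to neurons TCCA sites rose by 4.04 points less than GGG sites (difference -4.04, permutation p = 0.00085), between P17 and 6W the difference was 0.0510 points (permutation p = 0.971), and between P0 and 6W -8.42 points (permutation p = 0.00019). Sites are not independent replicates, and this contrast of contexts was chosen after the levels had been seen.

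**Figure D4:**
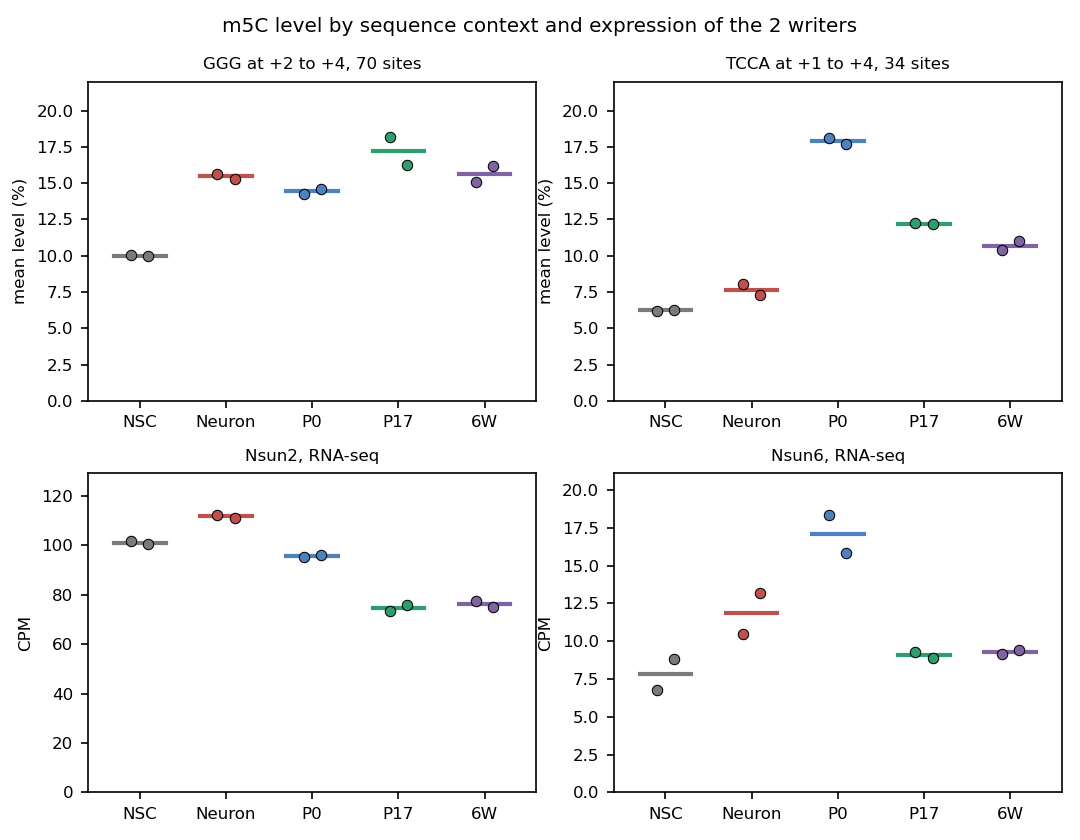
Mean m5C level in percent of sites followed by GGG (70 sites) or TCCA (34 sites) in each bisulfite library, above the CPM of the writer genes Nsun2 and Nsun6 in each RNA-seq library; points are libraries and lines are group means. TCCA sites and Nsun6 were both highest at P0, at 17.9% and 17.1 CPM.

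None of the 21 gene lists passed an adjusted p of 0.05 among the 2673 genes with a site in the table (Fisher's exact test against 19636 genes with a cytosine in a call table). The mature neuron and synapse list came closest, with 6 of 15 genes (Camk2b, Nefh, Nefm, Shank1, Syn1 and Syp; Fisher's exact test p = 0.0105, adjusted p = 0.221).

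Changes in m5C level and in expression were compared across genes, which are not independent replicates. Spearman's rho was 0.0661 for neurons against NSC (permutation p = 0.00586, adjusted 0.00796), 0.0703 for P17 against P0 (0.00131, adjusted 0.00524), -0.0407 for 6W against P17 (0.0526, adjusted 0.0526) and -0.0597 for 6W against P0 (0.00597, adjusted 0.00796); Pearson's r was -0.0054, 0.0413, -0.0475 and -0.0595 with adjusted permutation p of 0.824, 0.0791, 0.0478 and 0.0263. With 20 reads rho was 0.0307, 0.0385, -0.071 and -0.124, and the first 2 no longer passed (adjusted permutation p = 0.253 and 0.175). With sites found in both libraries of a group rho was 0.249, 0.232, 0.121 and 0.193, so that both 6W relations turned positive. Level and coverage in a group chose these sites, which can itself tie level to expression, so rho there cannot decide the direction. Without 6W replicate 2 the 6W relations over all tested sites stood at 0.0117 and 0.0533.

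The culture comparison was set against the postnatal one. Across 17336 genes the log2 fold change of neurons against NSC and that of P17 against P0 had a Spearman's rho of 0.0966 and a Pearson's r of 0.0796 (permutation p = 1e-05 for each, the smallest possible). Of the genes that rose in neurons 2785 also rose at P17, where 2356 would by chance, and of those that fell 2684 also fell, where 2420 would. Across 2114 m5C sites rho was 0.0337 (permutation p = 0.119) and r was -0.0549 (permutation p = 0.0119). Over the 348 of them found in both libraries of a group, an alternative chosen after the data were seen, rho turned to -0.154 (permutation p = 0.00409).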

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

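Of the tests below, the 3 on 6W replicate 2, the one on Nsun6 and the one on conversion in NSC were chosen only after the result was seen. Signal also appeared at positions that were counted per library but not tested as sites: 490 positions outside the authors' site table met the site rule in the call tables of all 10 libraries. Of these 260 are mitochondrial, and 98.8% have another listed position that meets the rule within 10 nucleotides, against 0 of the 37 positions of the site table that meet it in all 10.

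6W replicate 2 stood apart, with 2482 of the 4483 sites that met the rule in a single library. Incomplete conversion throughout that library is argued against as the source: its unconverted share at deeply covered cytosines (0.0879%), though above the 0.0757% to 0.0796% of the other brain libraries, exceeded that of replicate 1 by 0.0084 percentage points, where the mean level differed by 4.27 points. Methylation of the adult brain cannot be told apart from the other sources. Of the sites of replicate 2 with 20 reads in replicate 1, 14.8% met the rule there, against 39.5% or more in the other 9 such comparisons of replicates. Their median level there was 0%, against 3.70% to 12.4% in the others. Most sites of replicate 2 thus did not recur in replicate 1, but this restates that replicate 2 stood apart. Methylation of 1 animal alone would give the same values, so neither decides. Of the sites in replicate 2 alone 2.90% were followed by GGG and 0.970% by TCCA, nearer to the 1.85% and 0.808% of background cytosines than to the 24.1% and 7.96% of sites found in both libraries of a group, which leaves open methylation outside these contexts. Read or alignment errors stay open and may account for part of them, as 1.80% of the positions listed for this library had no cytosine in the genome, against 0.308% to 0.658% in the others. Methylation that differs between animals was not tested.

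Sites followed by TCCA were less methylated at P17 than at P0, by 5.69 percentage points on average, while GGG sites were not. TCCA sites found in NSC or neurons, without regard to the brain, changed by -8.92 percentage points (SE 4.67, n = 9 sites, 6 lower). This passed the limit set beforehand against a choice of sites for high values at P0. Such a choice is not ruled out, since the sites are few and include those of Sdc3 (-33.8 points) and Bag6 (-27.8 points). A shift in the cells that supply the transcripts cannot be told apart from a change within cells: sites in genes with stable expression changed by -3.89 points (SE 2.41, n = 16 sites, 10 lower), too few to decide. Lower expression of Nsun6, the writer for this context, is a candidate explanation, with a log2 fold change of -0.92 (SE 0.148), but neurons had more Nsun6 than the P17 brain (11.9 and 9.10 CPM) and lower TCCA levels (7.67% and 12.2%). The difference in age itself stays open.

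Sites found in both libraries of a group were less methylated in NSC than in neurons, by 5.70 percentage points over 375 sites. The choice of sites in neurons and brain is argued against, since the sites found in both NSC libraries were themselves 6.64 points higher in neurons (SE 1.49, n = 86 sites, 63 higher and 23 lower). The NSC counts of the site table, which equal those of the call tables at 56.5% to 62.4% of the listed sites, are argued against by a difference of 6.27 points with the counts of the call tables and 5.99 with those of the site table, over 289 sites. Fuller conversion in NSC is argued against by a difference in background of 0.0114 points. A biological difference between the cells is therefore a hypothesis that may hold; the origin of the cells, their sex makeup and culture conditions differ along with their type and were not told apart.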

How the results depend on the processing

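The count of genes that changed at least 2-fold was 8566 for neurons against NSC, 5505 for P17 against P0, 546 for 6W against P17 and 5934 for 6W against P0, fewer by construction. Changes from P17 to 6W numbered 3434 with limma on log2(TPM + 0.1), with more genes higher than lower there and at 2-fold, and 3538 to 4552 with 1 library left out (lowest without P17 replicate 2). With the other alternatives the 4 counts stayed within 1.5 times. Limma on TPM moved the median log2 fold change of P17 against P0 to -0.13 and -0.15. No named site reversed its direction under any alternative. Neither did any named gene past the threshold in the main fit or in the alternative, and the direction of the others was not compared. Of 237 entries of named genes over the 4 comparisons, 17 lost their call with limma on log2(TPM + 0.1), 7 on log2(TPM + 1) and 6 with DESeq2. With the replicate number as a block, 13450, 12122, 5275 and 12479 genes changed; residuals of equal replicate numbers were uncorrelated between groups (r from -0.052 to 0.034), so that the numbers do not pair the samples.

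For m5C sites the counts of neurons against NSC, P17 against P0, 6W against P17 and 6W against P0 moved with the test: 525, 660, 1408 and 1494 with Fisher's exact test on summed reads, which ignores replicates, and 7, 0, 0 and 12 with limma on arcsine square root levels, where the 2 counts of 0 had 294 and 103 sites at an unadjusted p under 0.05. Differences of at least 10 percentage points numbered 24, 42, 2 and 58, and sites found in both libraries of a group gave 127, 204, 63 and 215 with fewer sites tested. Levels in the groups compared helped choose the latter sites. The 4 libraries alone gave 117 and 146 for the first pair, the replicate block 157 for 6W against P0, and a single dispersion, chosen after the data were seen, 7 for 6W against P17. With 1 library left out, 6W against P17 gave 7 to 23 sites (lowest without 6W replicate 2). The cause of these moves was not tested.

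The site count per library passed only at positions of the authors' site table with 20 reads in all libraries (exact permutation p = 0.0339), which changes the list of positions and the depth at once; over all positions of the table p was 0.1619. The mean level passed with 20 and 30 reads (exact permutation p = 0.0339 and 0.0265) and, in alternatives chosen after the data were seen, for sites found in both libraries of a group (0.0063) and without sites of 6W replicate 2 alone (0.0476); with 1 library left out p ran from 0.0074 (without 6W replicate 1) to 0.3481 (0.0698 without 6W replicate 2), a lone library being assumed to vary like the others. The value of 0.0063 cannot test the groups, since agreement within the real groups chose those sites. The median level could not separate groups, being 0 in 9 libraries. The background p ran from 0.0011 to 0.1259 with 1 library left out, and lost its call without any NSC, neuron, P0 or P17 library. The background as first set, and its version with 30 reads, were not run. Camera called 43 lists over the 4 comparisons, and 20 with an estimated correlation. With the replicate number as a block the estimated correlation left calls for neurons against NSC alone (adjusted p = 0.0479 in camera).

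Spearman's correlation of m5C and expression changes was 0.0307 and 0.0385 for neurons against NSC and P17 against P0 with 20 reads, no longer past the threshold, and -0.071 for 6W against P17, now past it, and -0.1242 for 6W against P0, larger in size. For neurons against NSC it was 0.0661, and up to 0.1194 without neuron replicate 1. For sites found in both libraries of a group it reversed to 0.1211 for 6W against P17 and 0.1925 for 6W against P0. With 1 library left out it ran from -0.0503 (without 6W replicate 1) to 0.0117 for 6W against P17. For 6W against P0 it ran from -0.0684 to 0.0533, and both relations were positive without 6W replicate 2. Without P0 replicate 1 or 2 the call for 6W against P0 was lost even without adjustment over the comparisons (-0.039 and -0.0371). The culture and postnatal changes of sites had a rho of -0.1535 over sites found in both libraries of a group (permutation p = 0.00409) and -0.2294 over the 30 sites called in both (permutation p = 0.221). The cause was not tested. At named sites, limma lost 29 of 36 calls, the single dispersion 14, the replicate block 1, and leaving out a library 17 of 144.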

Other observations

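Some genes of smaller cell populations differed between the brain at birth and later. Kl, which encodes klotho and is expressed in the choroid plexus, went from 2.37 ± 0.126 CPM at P0 to 17.6 ± 6.35 at P17 and 24.5 ± 5.71 at 6W (SD, n = 2), not past the threshold in edgeR from P17 to 6W, while Folr1, a folate receptor gene of the same tissue, had a log2 fold change of -1.02 (SE 0.210) from P0 to 6W. The receptors for vascular endothelial growth factor parted: Flt1 was 2.52-fold higher and Kdr stood at 0.440 times its P0 level at 6W. From P17 to 6W the genes for the vesicular transporter and the synthesis of GABA, Slc32a1 and Gad1, were 1.37-fold and 1.22-fold higher, while 2 of the 10 GABAergic genes fell and the list did not pass camera (adjusted p = 0.865), and P2ry12 of microglia stood at 0.633 times its P17 level. The proteoglycan gene Vcan, counted here with oligodendrocyte precursors, went from 328 ± 3.55 CPM at P0 to 43.0 ± 1.69 at 6W.

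The dioxygenase genes moved apart in the culture comparison and together from P0 to 6W. Tet1 was 2.27-fold and Tet3 1.40-fold higher in neurons than in NSC, while Tet2 stood at 0.529 times its NSC level. Tet2 stood at 0.495 and Tet3 at 0.839 times its P0 level at P17, and Tet1 had a log2 fold change of 0.27 (SE 0.185), not past the threshold in edgeR (adjusted p = 0.248). At 6W all 3 were lower than at P0, Tet1 at 0.570, Tet2 at 0.522 and Tet3 at 0.605 times its level there. Of the genes for m6A, the demethylase gene Alkbh5 stood at 0.494 times its NSC level in neurons and the demethylase gene Fto was 1.67-fold higher, and Mettl3, the catalytic writer, was 1.70-fold higher at P17 than at P0 while Wtap, a subunit of the same complex, stood at 0.541 times its P0 level.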
